A study of Homo sapiens with 26 samples.

How the data were processed

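The deposited tables give, for 24 gradient fraction samples and 2 input samples of SK-MEL-28 cells, read counts per gene, which the authors made and did not normalize. Per the labels' protocols, libraries were made with a TruSeq stranded kit for total RNA. Per the submitters' processing notes, the tools were FastQC 0.11.5, STAR, SAMtools 0.1.19.24, HTSeq 0.5.3p3 and DESeq, with the human build hg19; the version of STAR and the strand setting of the counting are not given in the sources used here. All values used are counts as deposited. The fraction files have 56638 gene rows with human symbols, of which 33311 were matched to a RefSeq table of the assembly GRCh38, used for names and for which genes overlap each other only. Overlap was taken from position, without regard to strand. The input files have 55353 rows with mouse-style symbols, of which 30621 have names of the Gm or Rik kind. The reference behind the input rows is not given in the sources used here.

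Rows that name no gene (reads not aligned, not unique, ambiguous or outside features) were left out of library sizes and tests; gene rows held 4.72 to 5.79% of all counts in fraction files, 7.06% in the salubrinal input and 5.94% in the control input. Reads shared by near-identical genes, by overlapping genes or by antisense pairs may be placed on either row or on neither, and the row names below stand for rows of the files.

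Samples were grouped by treatment and fraction from their titles. Whether the 4 fraction files of a replicate number differ was tested by chi-square over rows outside ribosomal RNA with at least 10 counts. Nothing in the labels says that replicates are separate cultures, so p-values measure the spread between these samples only, which may be technical.

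Each fraction was compared between treatments with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, glmQLFit with robust estimation, quasi-likelihood test, Benjamini-Hochberg threshold 0.05), with 3 libraries per group. The difference of the treatment effect between fractions was tested as an interaction over 12 files. Outside ribosomal RNA rows these were counted as 6 libraries entered as 2 files each. Standard errors are the log2 fold change divided by the normal deviate of its p. CPM are scaled by TMM factors. The comparison of summed files used the same steps and was added after the data were seen. Of 32 gene lists, those with at least 5 tested rows were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives.

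The 2 input libraries were compared with no test. The log2 ratio is that of TMM-scaled counts with a prior count of 2. List members needed 50 counts over both libraries, and a list's median was set against 10000 random lists matched on expression in 20 bins. Intervals are exact conditional binomial ones at 95% and cover counting error only. Relations across genes were tested with 100000 permutations and given intervals from 2000 bootstrap draws.

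The rule for named rows was, for the polysome comparison, the 10 highest and 10 lowest log2 fold changes among rows past the threshold with a mean of at least 5 CPM and every treated library beyond every control library, which chance gives for 10% of rows at 3 against 3, and the 5 highest and 5 lowest for the other fractions; names of small RNAs, pseudogenes and unnamed transcripts were left out. For the summed comparison the polysome rule was used. For the input it was the 5 highest and 5 lowest ratios among rows with at least 200 counts, with mouse-style unnamed names left out (1000 of 6851 rows), and a fixed panel of ISR, melanoma and mitochondrial genes. Members of input lists are drawn from the 2 highest and 2 lowest, a choice made after the data were seen. Rows shown to illustrate overlap, and the overlap partners, were also chosen after their values were seen. The design, the rule, the gene lists and the alternatives not named as added were fixed before the data were examined.

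Alternatives were DESeq2 1.42.0, RLE size factors, no filter, a stricter filter (over 1 CPM and 50 counts), the removal of mitochondrial and small RNA rows, a replicate block, a joint fit of the 24 fraction files and leaving out each replicate. Added after the data were seen were library sizes alone, the removal of ribosomal RNA rows, the deepest 4 libraries (1 treated, 3 control) and all alternatives of the summed comparison. The comparison of treatments, not that of fractions, was checked on simulated counts: with 913 genes and the summed libraries it recovered 43.8%, 97.7% and 99.0% of genes changed by 1, 2 and 3 on the log2 scale, with 0.758% false calls, and with 241 genes and the polysome libraries 23.4%, 86.0% and 99.2%, with 1.47% false calls. Rows varied independently in the simulated counts, so these rates do not cover differences that many rows share between libraries. Random lists were checked with 20 simulated lists raised by 1, which all reached percentile 100, and 20 unchanged ones, which lay between 7.09 and 98.7. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the rest.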

Results

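RNA was measured in SK-MEL-28 cells, a human melanoma line, that had been left untreated or kept in salubrinal for 72 h. Salubrinal blocks the dephosphorylation of the translation factor eIF2α and so activates the integrated stress response (ISR), in which general protein synthesis falls while the mRNA of the transcription factor ATF4 is translated. Of the 26 samples, 13 were treated and 13 were not. For 24 of them lysates were spun through a sucrose gradient of 5 to 20%, after cycloheximide at 100 µg/mL for 12 min, and the gradient was collected as 4 fractions named 40S, 60S, 80S and polysome, with 3 replicates per fraction and treatment. The other 2 samples were input RNA, 1 per treatment. The cell-line field of the labels holds 26 different numbered names, while every title names SK-MEL-28, and the titles were followed. The question was which RNAs ribosomes hold in untreated cells and after ISR activation.

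The fraction files held 6627394 to 12984883 counts each, of which 81.6 to 92.8% were set aside as not uniquely placed and 4.72 to 5.79% fell on gene rows. The 28S ribosomal RNA row RNA28S5 took 92.4 to 98.3% of the gene-row counts. Outside ribosomal RNA (rRNA) rows 1120 to 23722 counts per file remained, spread over 250 to 3707 rows. The input files held 145107865 counts with salubrinal and 203322430 without, of which 10245548 and 12068784 fell on gene rows. Counts outside rRNA rows made up 1.69% ± 2.20 of gene-row counts in the treated and 3.56% ± 2.77 in the control libraries (SD, n = 3, the 4 files of a replicate summed; two-sided exact permutation p = 0.5, where the smallest possible p is 0.1).

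**Figure D1:**
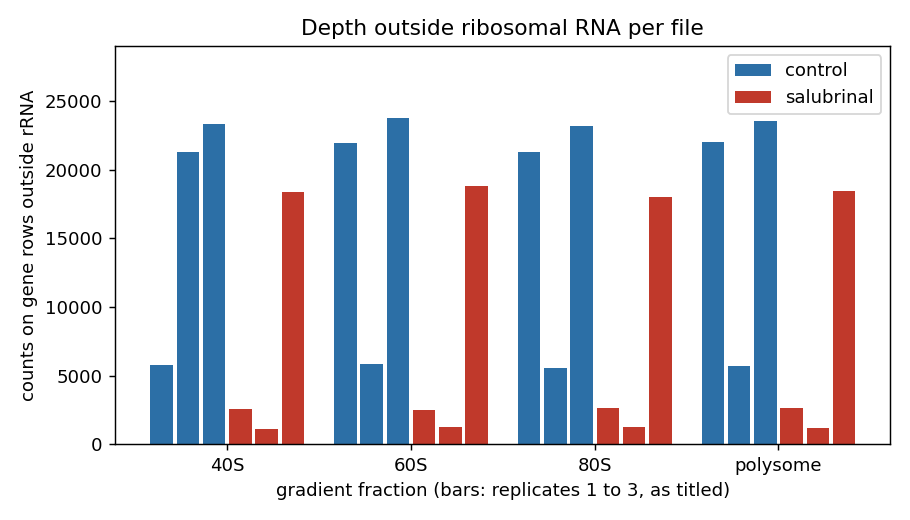
Counts on gene rows outside rRNA (vertical axis) in each fraction file, grouped by gradient fraction (horizontal axis), with 1 bar per replicate as titled and colours for treatment. The files range from 1120 to 23722 counts, and each library has nearly the same depth in all 4 fractions, except that the bars of control replicates 1 and 2 trade places in 40S.

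Most measured panel transcripts of the ISR were higher in the salubrinal input than in the control input. Asns, which encodes asparagine synthetase, stood at 355 CPM, counts scaled to library size, with salubrinal and 38.6 CPM without, a log2 ratio of 3.20 (95% interval 3.04 to 3.37). Atf4, the central transcription factor of the response, had a log2 ratio of 1.82 (1.73 to 1.91), and its partner Ddit3 (CHOP) one of 2.14, from 418 and 57 counts. The stress genes Chac1, Trib3 and Sesn2 were higher by 2.49, 2.26 and 2.19 on the log2 scale, and the cystine transporter gene Slc7a11 by 0.88. Atf5, whose mRNA is also translated during the ISR, was lower at -1.66 (-2.57 to -1.01), from 22 and 46 counts, and Ppp1r15a had 3 and 0 counts. There were no replicates of the input, so no test was made; intervals are exact binomial ones and cover counting error only. Row names in the 2 input files are mouse-style symbols and are given here as the files print them. If human reads were counted on a mouse reference, a possibility taken up below, a row with few counts need not mean low expression.

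Of the 33 measured ATF4 target genes, 20 were at least 2-fold higher with salubrinal and 0 were at least 2-fold lower. Their median log2 ratio of 1.15 lay at percentile 100 among 10000 random lists of equal size and expression, as a description of these libraries. Slc7a5, an amino acid transporter gene on the list, went the other way at -0.99. The 20 cytosolic tRNA synthetases had a median of 0.61 (percentile 100), with 5 at least 2-fold higher, led by Gars at 1.69 and Wars at 1.67, and Vars lowest at -0.39. Cytosolic ribosomal protein genes had a median of 0.35 over 61 members (percentile 100), none of them 2-fold apart. Genes of the unfolded protein response of the endoplasmic reticulum had a median of 0.26 (percentile 98.8), with Xbp1 at 1.85 and Sec24d at 1.77 but Sdf2l1 at -1.05 and Calr at -0.54. Targets of the antioxidant regulator NRF2 had a median of 0.36 (percentile 99.7), with Nqo1 at 1.11 and Gclm at 1.03 but Tkt at -0.86 and Osgin1 at -0.72.

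Pigment-cell genes were lower with salubrinal. The melanocytic list had a median of -0.77 over 26 measured members (percentile 0), with 10 at least 2-fold lower and 0 at least 2-fold higher. Trpm1, a melanocyte channel gene under the control of MITF, had a log2 ratio of -2.57 (-2.94 to -2.28), and Dct, which encodes a melanin-synthesis enzyme, -2.37 (-2.53 to -2.22). The lineage transcription factor genes Sox10 and Mitf stood at -1.46 and -1.01, while S100a1 on the same list stood at 0.83. The 15 measured genes of the undifferentiated melanoma state had a median of 0.25 (percentile 95.4), with Nrp1 at 2.25, Vegfa at 2.04 and Ngfr, a neural crest marker, at 1.06 (0.43 to 1.82), while Tead4 and Sox9 stood at -0.53 and -0.42. Axl, another marker of that state, had 0 and 2 counts, too few to tell its level.

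Cholesterol synthesis genes had the lowest median of the 24 lists with at least 5 measured members, -0.86 over 14 members (percentile 0) and 6 at least 2-fold lower, among them the master regulator Srebf2 at -1.66 and Dhcr7 at -1.55, with Fdft1 highest at 0.01. DNA replication genes had a median of -0.21 (percentile 0.44), with Cdt1 at -1.89 and Pold1 at -1.42 but Gins3 at 0.39 and Rfc4 at 0.37. The tricarboxylic acid cycle list had a median of -0.25 (percentile 0.87) and extracellular matrix genes one of -0.21 (percentile 0.65), in which Timp1 and Lama4 stood at 1.68 and 1.67 and Hspg2 and Col4a2 at -0.84 and -0.67. Of the mitochondrial lists, nuclear respiratory chain genes had a median of -0.11 (percentile 1.89) and mitoribosomal proteins 0.03 (percentile 63.4). Mitochondrial translation factors had a median of -0.08 (percentile 16.2), with the leucyl-tRNA synthetase row Lars2 at 1.43 and its methionyl counterpart Mars2 at -0.67. Lars2 had 18093 and 4130 counts with and without salubrinal, and Mars2 141 and 139. Whether all Lars2 reads come from that mRNA was not tested. The 5′ TOP translation factors, whose mRNAs respond to growth signals, had a median of 0.26, which 250 of the 10000 random lists reached, and mRNAs known to be translated during the ISR one of 0.30, which 251 reached. The lists of G2/M, p53 target, hypoxia and glycolysis, heat shock, proteasome, lysosome and autophagy, mitochondrial import and abundant small RNA genes lay between percentiles 3.35 and 83.4.

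**Figure D2:**
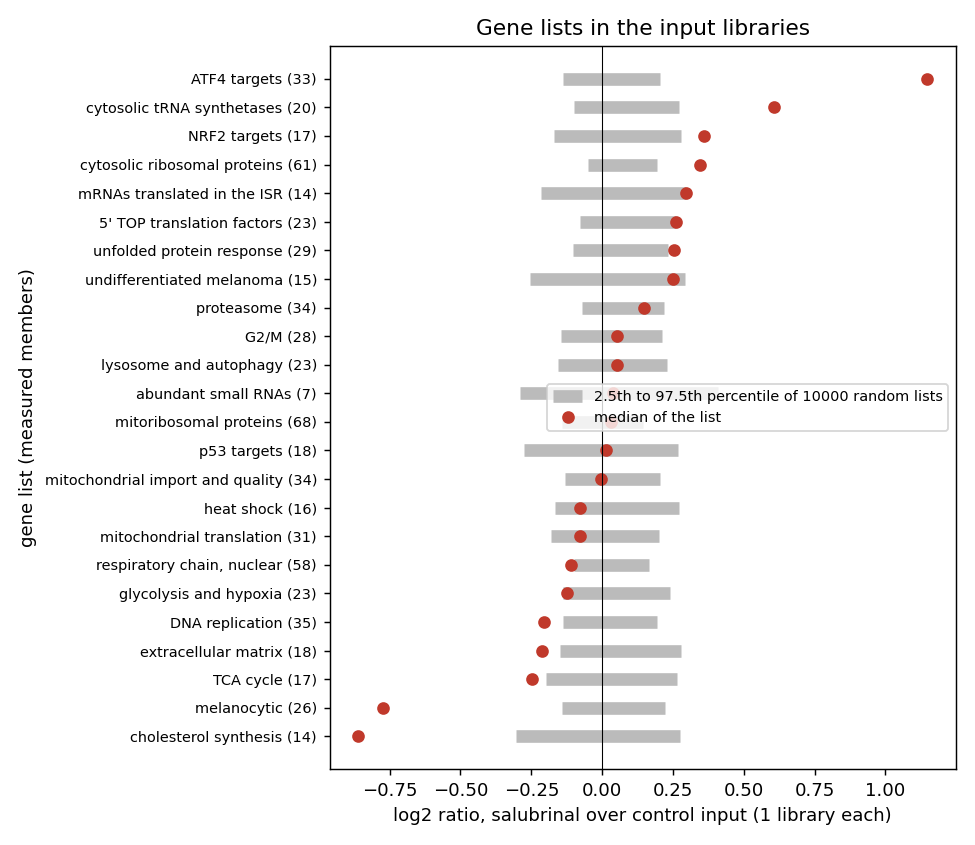
Median log2 ratio of salubrinal over control input (horizontal axis; 1 library each) for the 24 gene lists with at least 5 measured members (vertical axis, number of members in brackets). Red points are list medians, from -0.86 for cholesterol synthesis to 1.15 for ATF4 targets, and grey bars span the central 95% of 10000 random lists matched on size and expression.

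Among rows with at least 200 counts, 141 were at least 2-fold higher and 170 at least 2-fold lower with salubrinal, together 4.54% of 6851. The highest named rows were Sel1l3 (3.53), Asns, the cytokine gene Lif (2.54), the microtubule-associated protein gene Map1b (2.41) and S100a6 (2.26). The lowest were Chchd2 (-2.86), Trpm1, the focal adhesion gene Tns1 (-2.49), Dct and Repin1 (-2.13). Scaling by total counts in place of trimmed means (TMM) moved the median of all rows by 0.93, and gave 3321 rows higher and 8 lower. Under it 10 of the 24 list medians turned positive, including the melanocytic (0.16) and cholesterol (0.07) ones, but all 10 stayed below the shift, and relative to it no list changed sign. The row CT010467.1 took 12.8% of the gene-row counts with salubrinal and 56.7% without, and mt-Rnr2 17.8 and 8.85%. Of all counts in the salubrinal and control input files, 27.3 and 14.4% were not aligned and 3.54 and 9.50% were ambiguous.

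Outside rRNA rows, the 4 fraction files of each replicate held the same counts within sampling noise. There, chi-square per degree of freedom across the 4 files was 0.963 to 1.04 in the 6 sets (p from 0.0778 to 0.808; smallest Benjamini-Hochberg p = 0.467), while it was 1.76 to 11.5 between the 3 replicates within a fraction. With the rRNA rows it was 0.996 to 3.77, and 4 of the 6 sets differed beyond sampling at a Benjamini-Hochberg threshold of 0.05; the share of the 18S row in treated replicate 1, for example, was 1.82% in 40S and 2.30% in polysome. File totals stood in near-constant proportion, at 0.973 to 0.982 of the 60S file for 40S, 0.966 to 0.977 for 80S and 0.985 to 0.991 for polysome. In the control group the 40S files titled replicates 1 and 2 matched the other fractions of replicates 2 and 1. The 6 sets were formed with these files so placed, by the same statistic. As titled, 40S against 60S gave 2.22 for control 1 and 2.31 for control 2. On the rows outside rRNA the 24 files were counted as 6 libraries, 3 per treatment, a choice that the rRNA rows do not settle. Each fraction is still reported as designed, and a comparison with the 4 files of a library summed into 1 replicate was added after the data were seen.

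**Figure D3:**
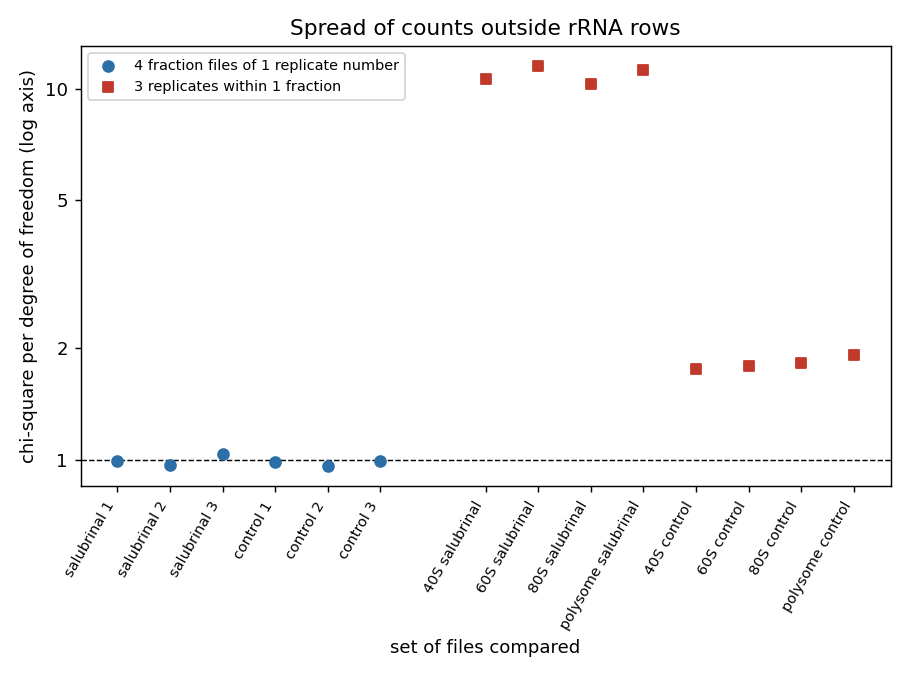
Chi-square per degree of freedom of counts outside rRNA rows (vertical, log axis), for the 4 fraction files of 1 replicate number (circles) and for the 3 replicates within 1 fraction (squares), with the compared set on the horizontal axis. The dashed line at 1 marks sampling noise alone; the circles lie between 0.963 and 1.04 and the squares between 1.76 and 11.5.

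Many of the highest rows in the fraction files overlap abundant genes whose own rows held few counts, but ENO3 (823 counts), GPS2 (695), ORAOV1 (513), JSRP1 (465) and PMEL (343) overlap no gene in the table used. Of 124 antisense pairs with at least 24 counts, 94 had the higher count on the antisense row, with 15372 counts on antisense and 7084 on sense rows; CEBPZ, with 217 sense and 102 antisense counts, was among the others. At the extreme, VIM, which encodes the filament protein vimentin, had 23 counts over the 24 files and its antisense row VIM-AS1 had 6280. GAPDH had 12 against 14209 on the overlapping row RP5-940J5.9, FTH1 had 93 against 3655 on BEST1, and SQSTM1 had 43 against 4283 on C5orf45. The 100 most abundant protein-coding genes of the input had a median of 4 counts and held 0.395% of counts outside rRNA, against 21.8% of input counts. Across 1398 overlapping pairs of protein-coding genes, a row's count was related to the input level of the overlapping gene (Spearman rho = 0.295, permutation p = 1e-05, the smallest that 100000 permutations can give) and not to that of its own gene (rho = -0.0247, p = 0.356), and the relations are across genes, which are not independent replicates. The 21.8% and both rho values set input levels of different genes side by side, and those levels depend on a reference with mouse-style names. ISR transcripts had few counts over the 24 fraction files, with 37 on DDIT3, 25 on ATF5, 1 on ATF4 and 0 on ASNS, CHAC1 and SESN2, and none of these rows had enough to be tested.

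In the polysome files the mitochondrial row MT-ND4, named for a subunit of respiratory complex I, rose with salubrinal from 8.42 ± 6.22 to 50.7 ± 34.5 CPM (SD, n = 3), a log2 fold change of 2.16 ± 0.52 (SE; edgeR adjusted p = 0.00884). GAS5-AS1, which overlaps the growth-arrest RNA gene GAS5, rose by 1.46 ± 0.42 (adjusted p = 0.0365). PMEL, the row of a melanosome protein gene, fell by 1.66 ± 0.51 (adjusted p = 0.0368), from 20.4 ± 2.01 to 4.22 ± 3.74 CPM. Counts were low: PMEL held 10 in the treated and 78 in the control polysome files, and GAS5-AS1 held 40 and 35. TMM factors ran from 0.10 in treated replicate 2 to 4.69 in control replicate 3, so these changes rest on the scaling. The fixed panel rows MT-CO1 (1.01), MT-ND1 (1.23) and MT-RNR2 (0.71) did not pass, at adjusted p = 0.152, 0.108 and 0.518. In all, 9 of 241 tested rows passed, 6 higher and 3 lower, and the other 6 have names of small or unnamed RNAs that the naming rule leaves out.

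The polysome count depended on single libraries, on the rows kept and on the scaling. Removing mitochondrial and small RNA rows gave 27 calls, 17 higher and 10 lower, and removing rRNA rows, an alternative added after the data were seen, gave 19, 12 higher and 7 lower. Leaving out treated replicate 1, 2 or 3 gave 3, 39 or 4 calls, and leaving out control replicate 1, 2 or 3 gave 0, 5 or 0, the zeros with edgeR's test and with 22 and 28 rows at an unadjusted p under 0.05. DESeq2, here and below run without the low-count filter, called 0 of 6044 rows (57 at an unadjusted p under 0.05). Without the filter edgeR also called 0 of 6044, so the tool was not tested apart from the filter. On library sizes alone edgeR called 0 (0 at that level), with the median of all tested rows moved by -1.09. Against that shift MT-ND1 at -0.13 and MT-RNR2 at -0.10 changed sign but stayed above it.

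In the 80S files 27 of 213 rows passed, 16 higher and 11 lower. GAS5-AS1 rose by 1.63 ± 0.40 (adjusted p = 0.0018), from 8.52 ± 4.03 to 29.5 ± 16.8 CPM. The complex I rows MT-ND2 (1.57 ± 0.48), MT-ND4 (1.34 ± 0.44) and MT-ND1 (1.29 ± 0.43) rose, as did S100A13, a calcium-binding protein row (1.47 ± 0.40). PMEL fell by 1.88 ± 0.46 (adjusted p = 0.0018), and FAM166A, TMEM79, MFSD11 and MYEF2 fell by 1.51, 1.46, 1.46 and 1.38. MYEF2 overlaps the pigmentation gene SLC24A5, and MFSD11 the splicing factor gene SRSF2. DESeq2 called 0 rows (59 at an unadjusted p under 0.05); the counts without treated replicate 1, 2 or 3 were 11, 46 and 4, and without control replicate 1, 2 or 3 they were 1, 4 and 0 (edgeR, 39 rows at an unadjusted p under 0.05 at the 0). The split of calls depended on scaling: with RLE size factors it was 11 higher and 21 lower, and the median of all rows moved by -0.20.

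In the 60S files 23 of 234 rows passed, 16 higher and 7 lower. MCMDC2, whose row overlaps the snoRNA host gene SNHG6, rose by 1.71 ± 0.39 (adjusted p = 0.00226), from 17.6 ± 2.38 to 59.3 ± 14.5 CPM. ATG10, MT-ND4, MT-ND1 and SH3D19 rose by 1.62, 1.62, 1.60 and 1.48. PIGF, whose row overlaps the small GTPase gene RHOQ, fell by 1.42 ± 0.42 (adjusted p = 0.0172), and MYEF2 fell by 1.30 ± 0.43. DESeq2 called 0 rows (45 at an unadjusted p under 0.05); the counts were 0, 39 and 5 without treated replicate 1, 2 or 3 and 0, 0 and 0 without control replicate 1, 2 or 3 (edgeR, 47, 36, 50 and 30 rows at an unadjusted p under 0.05 at the zeros). With RLE size factors 11 rows were higher and 15 lower, with a shift of the median of -0.20.

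In the 40S files 18 of 225 rows passed, 14 higher and 4 lower. MT-ND4, MCMDC2 and MT-ND1 rose by 1.34 ± 0.45, 1.31 ± 0.45 and 1.30 ± 0.45 (adjusted p = 0.045, 0.0451 and 0.0451). PMEL fell by 1.82 ± 0.48 (adjusted p = 0.0083), and MFSD11 and MYEF2 fell by 1.47 and 1.39. DESeq2 called 0 rows (53 at an unadjusted p under 0.05); the counts without treated replicate 2 or 3 were 47 and 3, and without control replicate 2 or 3 as titled 0 and 3 (edgeR, 24 rows at an unadjusted p under 0.05 at the 0). With RLE size factors 13 rows were higher and 14 lower, with a shift of -0.13; with library sizes alone the median moved by -1.10, and MT-ND1 (-0.0095) and MCMDC2 (-0.022) changed sign but stayed above that shift. Across the 4 fractions 39 rows were called at least once and 3 in every one, of 160 tested in all. These 3 rows, named here after their values were seen, were MT-ND4 and the unnamed transcripts RP11-287D1.3 and RP11-290D2.6. Outside rRNA rows the fractions hold the same counts within sampling noise, so the calls are not taken as independent.

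With the 4 files of each library summed, MT-ND4 rose as in every single fraction, and PMEL fell as in polysome, 80S and 40S. In 60S PMEL did not pass (-0.65, edgeR adjusted p = 0.469). The sum is made of the same counts as the single files, so it is no further evidence for either row. MT-CO3, named for a subunit of cytochrome c oxidase, rose from 5.62 ± 2.41 to 23.1 ± 4.80 CPM (SD, n = 3), a log2 fold change of 2.03 ± 0.36 (adjusted p = 1.42e-05). MT-ND4, MT-CO2, MT-ND3, MT-ND1 and MT-ND2 rose by 2.25, 2.21, 1.93, 1.75 and 1.56, and MT-CO1 by 1.07 (adjusted p = 0.0434), while the mitochondrial rRNA rows MT-RNR1 (0.50) and MT-RNR2 (1.03) did not pass, at adjusted p = 0.634 and 0.152. MARS rose by 1.70 ± 0.41 (adjusted p = 0.00214); its row overlaps the stress gene DDIT3. ATG10, S100A13 and MCMDC2 rose by 1.77, 1.53 and 1.48. PMEL fell by 1.45 ± 0.39 (adjusted p = 0.00776), and MFSD11, TMEM79, SLC7A6, PHYKPL and MARCH7 fell by 1.45, 1.38, 1.32, 1.26 and 1.21; DAK also fell (adjusted p = 0.00851), and MYEF2 at -1.22 did not pass (adjusted p = 0.0913).

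In this summed comparison 52 of 913 rows passed, 33 higher and 19 lower. Of the 9 polysome calls 8 were among them, but the polysome counts are part of the sum. DESeq2, run without the low-count filter, called 18 rows, so tool and filter changed together. With library sizes alone edgeR called 0 (0 rows at an unadjusted p under 0.05), with the median of all rows moved by -1.23 and MT-RNR1 at -0.73. Without treated replicate 2 or 3 the count was 117 and 15, and without control replicate 1 or 3 it was 8 and 8.

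**Figure D4:**
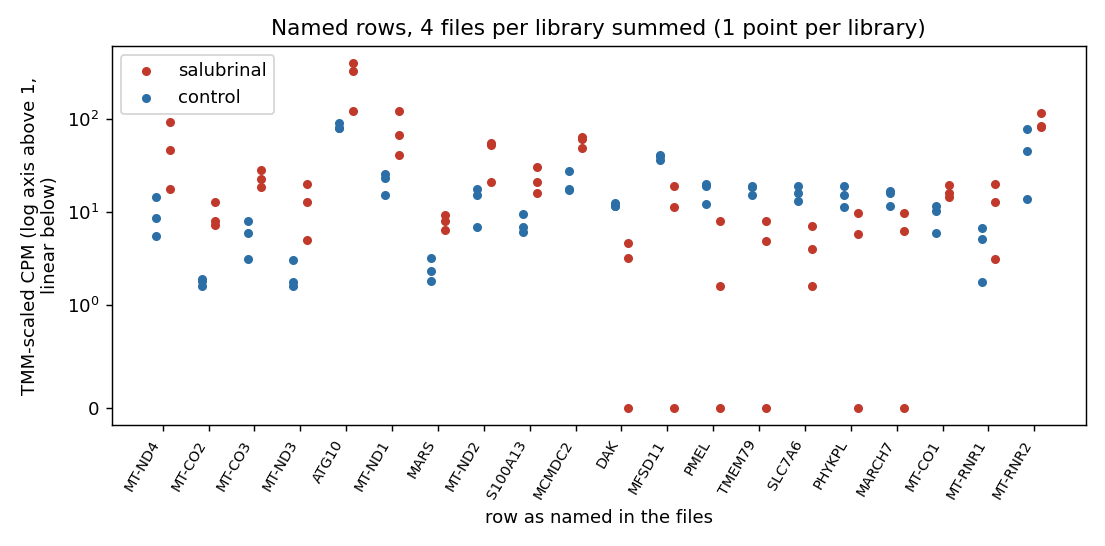
TMM-scaled CPM (vertical axis, logarithmic above 1 and linear below) of the named rows (horizontal axis) with the 4 files of each library summed; each point is 1 of 3 libraries per treatment. The treated libraries lie above every control library for rows such as MT-ND4, MT-CO2, MT-CO3 and MARS and below for rows such as PMEL and DAK. The naming rule required this separation of all rows shown but the fixed panel rows MT-CO1, MT-RNR1 and MT-RNR2, so it is not a result.

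Of the 32 gene lists, the mitochondrially encoded mRNAs alone had at least 5 tested rows in the fraction files. In the polysome files their 7 tested rows had a median log2 fold change of 1.23, with 1 row past the threshold over all rows and 5 when adjusted over the list alone (camera adjusted p = 1.32e-06; adjusted p = 0.0833 with an estimated correlation). In 80S the median was 1.34, with 5 rows past the threshold and 5 adjusted over the list alone (camera adjusted p = 3.73e-06; adjusted p = 0.0456 with an estimated correlation). In 60S the median was 1.39, with 3 and, adjusted over the list alone, 5 (camera adjusted p = 1.01e-05; adjusted p = 0.0949 with an estimated correlation). In 40S it was 1.19, with 3 and, adjusted over the list alone, 4 (camera adjusted p = 5.08e-05; adjusted p = 0.0689 with an estimated correlation). Summed, 7 of 10 tested rows rose and 10 passed when adjusted over the list alone, with a median of 1.84. The camera adjusted p was 1.91e-15 at the preset correlation and 0.0185 with an estimated one. With fry p was 0.104 in polysome, 0.0335 in 80S, 0.0818 in 60S, 0.0705 in 40S and 0.0175 summed. Only this list was tested, so adjustment changed no p. Of the 10 splits of the libraries into 3 and 3, the real one included, 6 or 7 called the list in each comparison. Its call at the preset correlation therefore does not mark treatment. The row MT-ND6, which lies on the opposite strand of the mitochondrial genome from the other mRNAs, held 2944 counts over the 24 files. These were 39.0% of all counts on mitochondrial mRNA rows. If reads were counted on the opposite strand, which is not settled, each row would hold RNA of the strand opposite to its mRNA. The rise is therefore one of rows, and whether these mRNAs rose is not known. The treated library of lowest depth, replicate 2, had the highest summed MT-ND4 level, at 92.5 CPM against 46.6 and 17.5 in the other treated and 5.47 to 14.5 in the control libraries. Other rows also lay highest in the library of lowest depth of each treatment, replicate 2 in both, with MT-ND6 at 2554 CPM against 423 and 105 in the treated and 345 against 84.7 and 45.8 in the control libraries. The nuclear rRNA rows had the same order and high summed log2 fold changes, 3.06 for RNA18S5 and 2.71 for RNA28S5, which did not pass (adjusted p = 0.202 and 0.557). In the input, where 9 of the 13 mitochondrial mRNA rows had under 100 counts over both libraries, mt-Nd5 stood at -1.26, mt-Nd6 at -0.79, mt-Nd1 at -0.41 and mt-Co1 at -0.35.

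No named gene separated the fractions. The effect of salubrinal differed between polysome and 80S for 0 of 395 rows (edgeR, 11 at an unadjusted p under 0.05; DESeq2 0, with 4), and between polysome and 40S for 0 of 399 rows (edgeR, 7; DESeq2 0, with 0). In untreated cells, polysome and 40S differed for 0 of 387 rows (edgeR, 7 at an unadjusted p under 0.05; DESeq2 0, with 3), with a median log2 fold change of 0.00. DESeq2 was run without the low-count filter, so its rows are not those counted for edgeR. The tests of a differing effect used 12 files. Outside rRNA rows these were counted as 6 libraries entered as 2 files each, so the files are not 12 independent samples. There the files compared held the same counts within sampling noise, so these tests could hardly return anything but 0, whatever salubrinal does. They do not show that RNAs stayed in their fractions. The size of difference that these tests could find was not simulated.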

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

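Alternatives added after the data were seen are library sizes alone, removal of ribosomal RNA rows, the deepest libraries, and those of the summed comparison and of the input rows at least 2-fold apart. Calls per comparison are given for polysome, 80S, 60S, 40S and summed files, whose values were 9, 27, 23, 18 and 52. DESeq2, which was run with no filter, gave 0, 0, 0, 0 and 18, and edgeR with no filter 0, 0, 0, 1 and 4. The stricter filter gave 0, 0, 4, 0 and 19, and library sizes alone 0 in each. Removing ribosomal RNA rows gave 19, 30, 41, 45 and 89, the deepest libraries, 1 treated (replicate 3) against 3 controls, so that treatment and that library are the same, 25, 55, 41, 51 and 110, and removing mitochondrial and small RNA rows 27, 30, 31, 24 and 62. The joint fit gave 7, 9, 6 and 26 for the 4 fractions, largely of other rows. Of its polysome and 80S calls, 1 and 3 were also calls of the single fits. In the joint fit 23 of 29 values of named rows lost the call. Leaving out each replicate gave 0 to 39, 0 to 46, 0 to 39, 0 to 47 and 8 to 117. The stricter filter left 13 to 17 rows to test in a fraction, so that few could be called, and the cause of the other changes was not tested. The tests between fractions and of polysome against 40S in control cells gave 0 under every alternative. Files with the same counts outside ribosomal RNA rows would give this whatever the treatment does. The call of the mitochondrial mRNA list was kept in every fraction and in the summed files with RLE size factors, with the block and without each replicate, and became 0 in polysome, 60S and 40S with an estimated correlation and with fry. Of 698 values of named rows under alternatives, 317 kept direction and side of the threshold, 375 lost the call, 0 gained one and 6 changed sign. With library sizes alone the sign changed for MT-ND1 (-0.13) and MT-RNR2 (-0.10) in polysome, MCMDC2 (-0.022) and MT-ND1 (-0.0095) in 40S and MT-RNR1 (-0.73) in the summed files, against shifts of the median of all rows of -1.09, -1.10 and -1.23; with the deepest libraries it changed for MT-RNR1 (-0.24). In the input, total counts in place of TMM gave an ATF4 target median of 2.09 and 3329 rows at least 2-fold apart, against 1.15 and 311. The lowest fraction file held 1120 counts outside ribosomal RNA.

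With the replicate number as a block, calls were 4, 15, 9, 0 and 24, and 0 in 40S with the control numbers of the file names (edgeR, 29 and 37 rows at an unadjusted p under 0.05). Nothing in the labels pairs the numbers. Correlations of deviations for numbers 1, 2 and 3 were 0.02, 0.35 and 0.42 in polysome, -0.04, 0.37 and 0.55 in 80S, 0.00, 0.35 and 0.52 in 60S, -0.04, -0.29 and 0.48 in 40S as titled and 0.01, 0.44 and 0.48 in 40S with the numbers of the file names. The block was set as an alternative before the data were examined. Number 1 showed no shared deviation, while numbers 2 and 3 did, except number 2 in 40S as titled. Whether the fits with or without the block are the better ones is therefore open.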

Other observations

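All tests of explanations here were chosen after the result was seen, except the counts over other splits of the samples for the planned comparisons; the summed comparison was itself added after the data were seen.

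Other input genes that differed between the 2 libraries, some of them members of the fixed lists, are named here after their values were seen. Serpine2 and Igfbp3, which encode secreted proteins, stood at 1.92 and 1.59 on the log2 scale, and the metabolic genes Nnmt, Aldh1l2 and Aldh1a3 at 2.09, 2.21 and 1.63. The mitochondrial folate enzyme gene Mthfd2 and the serine synthesis gene Psat1 stood at 1.64 and 1.40. The fatty acid synthesis genes Fasn and Scd1 stood at -1.65 and -1.28, and the pigmentation genes Oca2 and Slc45a2 at -1.64 and -1.51. These are values of 1 library per treatment.

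Outside ribosomal RNA rows the 4 fraction files of a replicate hold the same counts within sampling noise. There, 4 separately prepared libraries would differ beyond sampling in at least 1 set, but the smallest Benjamini-Hochberg p over the 6 sets was 0.467, while replicates within a fraction differed; a candidate explanation is 1 library read in 4 portions, such as sequencing lanes, with a highest chi-square per degree of freedom of 1.04. Sampling from 1 library is not enough for the ribosomal RNA rows, with which the highest value was 3.77 and 4 of the 6 sets differed. For these rows separate libraries and lanes of unequal quality cannot be told apart: the 18S share was higher in 40S than in 60S in 1 of 6 sets, but the kit and the placement of reads can shift it, and the share of unaligned reads was highest in the polysome file in 6 of 6 sets, at 1.09 to 1.34 times that of 40S. No biological explanation was tested, and whether the 6 libraries are of a fraction or of a pool stays open.

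Many of the fraction counts lie on rows that overlap abundant genes. Rows such as ENO3 (823 counts) and PMEL (343) overlap no gene in the RefSeq table used, and SH3D19 (1936) overlaps a protein-coding gene with 0 input counts. That table matched 33311 of the 56638 row symbols, so overlaps with unmatched rows would be missed. Low depth alone would keep the share of the most abundant genes, yet the 100 most abundant genes of the input held 0.395% of counts outside ribosomal RNA, against 21.8% in the input. Counting with the opposite strand setting for a stranded library may explain part of it: rows tracked the overlapping gene better than their own, with a difference of rho of 0.320 (95% bootstrap interval 0.243 to 0.392). Overlap was taken from position without regard to strand, so this difference alone does not test strand. The kit is stranded per the labels. No biological explanation was tested.

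A hypothesis that follows is that the changes on these rows with salubrinal are those of the RNA of the overlapping gene. Across 282 tested rows of the summed files with 1 overlapping gene measured in the input, log2 fold changes were related to the input log2 ratio of that gene (Spearman rho = 0.207, permutation p = 0.00047, adjusted p = 0.00114 over 3 relations; 95% bootstrap interval 0.0892 to 0.320). The idea came from called rows, and without them rho was 0.198 over 275 rows (permutation p = 0.00076, adjusted p = 0.00114). For the gene a row is named for, rho was 0.0068 over 234 rows (permutation p = 0.915, adjusted p = 0.915; interval -0.119 to 0.131), which leaves a weak relation open. In both relations names were also matched through synonyms, so some rows took the value of another gene, such as SLA2 that of Mars (1.35). Among called rows, SLC4A5 (1.55) overlaps MTHFD2 (1.64 in the input) and SLC7A11-AS1 (1.02) overlaps SLC7A11 (0.88), while B3GAT2 (-1.48) overlaps SMAP1 (0.45 in the input). In all, 5 of 7 went the way of the overlapping gene, among them TMEM79 (-1.38), whose overlapping gene SMG5 stood at -0.05. Of the named called rows, S100A13, MARS, PMEL, SLC7A6, ATG10 and MFSD11 went the way of their own gene in the input. PHYKPL and MARCH7 did not. MFSD11 also went the way of its overlapping gene SRSF2 (-0.27), and PHYKPL went against its overlapping gene HNRNPAB (0.17). The tally of 5 of 7 covers called rows with 1 overlapping gene measured, and the tally by own gene only named rows. These sets differ, so the called rows do not settle which gene they follow. The fraction rows may carry part of the changes seen in the input, across genes that are not independent replicates. Whether ISR genes have a share in this relation was not tested.

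The input files name mouse genes although the labels give human cells. Mouse cells would fill the rows of respiratory chain subunits, which every cell makes, but 17 of 75 had under 50 counts, among them Cox6c with 2 and Ndufa4 with 3, beside 1012 on Cox4i1; near-identical gene copies could empty some of these rows. Human rows renamed to mouse symbols would leave Gm and Rik rows empty, but 1752 of them had at least 50 counts. Human reads counted on a mouse reference may explain the names: 9 of the 13 mitochondrial mRNA rows had under 100 counts, with 58 on mt-Cytb, while mt-Rnr2 had 2888691. Under that reading a gene's count depends on how alike the species are. This limits the 21.8% share and the relations of counts to input levels across genes given above. Whether it acts alike in both libraries was not tested. Of the salubrinal and control input counts, 27.3 and 14.4% were not aligned, so the log2 ratios may be affected too.

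With 3 libraries against 3 there are 10 splits, so the share of splits with as many calls cannot go under 0.1. The real count and the highest of the other splits were 9 and 8 for polysome, 27 and 7 for 80S, 23 and 7 for 60S, 18 and 6 for 40S, and 52 and 9 for the summed files, with 1 split at the real count in each. For the gene lists the real and the highest other count were 1 and 1 in each case, reached in 7, 6, 7, 7 and 7 of the 10 splits. For the difference between polysome and 80S and between polysome and 40S both were 0, in 10 of 10 splits, and for polysome against 40S in control cells they were 0 and 2.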
